A study of Homo sapiens with 6 samples.

How the data were processed

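Messenger RNA was sequenced from Jurkat cells, a human T lymphocyte line derived from a leukemia, in 3 libraries exposed to the vehicle dimethyl sulfoxide (DMSO, 0.1%) and 3 exposed to 1 µM bisphenol AF (BPAF), a fluorinated analogue of bisphenol A. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads and made into stranded paired-end libraries that were read on an Illumina NovaSeq instrument. The labels disagree on the exposure time: the treatment label of each sample and the design text give 12 h, and the treatment protocol gives 24 h. The design text calls the 3 libraries of a group biological replicates.

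The submitters' processing notes name FastQC, cutadapt, HISAT2 and featureCounts and the human builds GRCh38 and hg38, without versions. The deposited count table held estimated counts per gene with decimals, and 59.6% to 61.0% of the values above 0 were whole numbers on average in the BPAF and DMSO libraries (tolerance 1e-09). How fractional values arose is not given in the sources used here. The deposited TPM table held TPM values (transcript abundance scaled for gene length) that summed to the same total in each library, and how they were computed is not given in the sources used here. Both tables listed 60856 features, of which 60664 carried Ensembl gene identifiers. The other 192 were assembled loci without a gene identifier, and they took 0.248% of DMSO counts and 0.258% of BPAF counts on average. Gene symbols were found for 42028 identifiers, and 58396 were present in GENCODE release 29 (GRCh38), which supplied coordinates, gene classes, exon lengths and GC content. Exon length was the union of all annotated exons of a gene, and GC content that of its longest transcript. The annotation used for the deposited counts is not given in the sources used here, so these coordinates describe the matched identifiers only.

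Estimated counts were rounded to whole numbers, which gave totals of 20253656 to 22617613 per library. Genes were filtered with filterByExpr, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with robust dispersion estimates and no covariate. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. Levels are TMM-scaled CPM (counts scaled to a common library total) with the SD of 3 libraries. Dispersion among replicates was low, with a biological coefficient of variation of 3.77%.

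Before the data were examined, 37 gene lists were written from general knowledge. They covered estrogen, inflammatory and T-cell biology, stress, metabolism, the cell cycle, ribosomes, mitochondria and markers of other cell types. The 33 lists with at least 5 tested members were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01. They were tested again with the correlation estimated for each list and with a rotation test (fry). With an estimated correlation, camera rests on the few residual degrees of freedom of 6 libraries, and its smallest adjusted p over the 33 lists was 0.366. The T-cell activation list had that value although its estimated correlation, 0.0017, was under the preset 0.01. Not passing with an estimated correlation therefore does not show that correlation explains a shift. The genes named were the 10 largest rises and the 10 largest falls among genes with a symbol, an adjusted p past the threshold, an average log2 CPM of at least 1 and no overlap between the groups. The receptors ESR1, ESR2, GPER1 and ESRRA were added whatever their values, as were up to 4 members with the smallest p from each list described. Single library measures were compared with a two-sided exact permutation test, whose smallest possible p for 3 against 3 is 0.1. These were computed in Python 3.11.15 with numpy 2.4.6.

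Alternatives covered size factors (RLE), upper quartile scaling, other filters, DESeq2 1.42.0, limma-voom, limma on log2 of the deposited TPM plus 1 or 0.1, the replicate number as a block, and each library left out in turn. Annotated genes only, protein-coding genes only, an offset for exon length and GC content, and DESeq2 without independent filtering were added after the data had been seen. With that offset, camera was run on log2 CPM less the fitted length and GC terms, not on voom values. Libraries were compared pairwise, and no pair agreed within sampling noise (chi-square per degree of freedom from 2.45 to 8.49). The tests were checked on simulated counts in which 200 genes were changed. They recovered 51% of 1.2-fold, 71.5% of 1.5-fold and 93.5% of 2-fold changes, with 4.67%, 4.67% and 2.09% false calls. The changed genes were drawn from those above a minimum mean count, and no gene was given a dispersion of its own. These rates therefore may not hold for genes with low counts or high variability. In 10 simulations with the ribosomal protein list lowered by 0.15 on the log2 scale, camera recovered that list in 10. Other lists were called 1 time in total over the 10 simulations. Genes were drawn independently there, whereas the estimated correlation of the real ribosomal protein list was 0.81. The simulations therefore do not measure false calls among correlated genes. Of the genes tested, 3 members of the lists are not reported here by name and stay in every fit and count.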

Results

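Jurkat T cells were profiled by RNA sequencing to learn which transcripts respond to bisphenol AF (BPAF), with the series title placing the question in estrogen signalling and inflammation. The 3 DMSO libraries held 22117976, 20745097 and 20935609 counts, and the 3 BPAF libraries held 21378320, 20253656 and 22617613. Library totals overlapped between the groups (two-sided exact permutation p = 0.9). A count above 0 was found for 22861 ± 208 genes in DMSO and 23539 ± 196 in BPAF (SD, n = 3), with no overlap between groups and the smallest exact permutation p that 3 against 3 allows, 0.1. The first principal component, with 27.3% of the variance, separated the groups.

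BPAF was accompanied by many small changes: 411 genes rose and 527 fell among 15490 tested, with a median size of 0.21 on the log2 scale (edgeR quasi-likelihood test, Benjamini-Hochberg). Of these, 28 changed at least 2-fold, 22 of them upward. Genes of the immediate early response, including FOS, JUN and DUSP2, were among the larger falls. Of 76 ribosomal protein and 58 respiratory chain genes, 36 and 14 fell, by small amounts, and neither list passed with an estimated correlation (adjusted p = 0.378 and 0.380). Long non-coding RNAs and pseudogenes made up 107 and 49 of the 411 rises. Groups did not overlap for 24.8% of tested genes, against 10% by chance. Upper quartile scaling gave 461 higher and 400 lower, and an offset for exon length and GC content gave 284 higher and 1204 lower. That offset also moved the median log2 fold change of all tested genes from 0.0019 to -0.043, so its balance of calls partly reflects a common shift. DESeq2 gave 164 higher and 467 lower among the 6765 genes its own filter kept, and called 550 of the 15490 genes without that filter, 358 of them lower. Limma on the deposited TPM called 0 to 2 genes while 2520 to 3100 had an unadjusted p under 0.05. The count from edgeR was 322 without BPAF replicate 1, 392 without BPAF replicate 3 and 482 without DMSO replicate 1.

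Among genes with an average log2 CPM of at least 1, the largest named rises were those of C1QTNF3, which encodes a secreted protein of the C1q and TNF related family, and ZNF395, which encodes a zinc finger protein. ZNF395 (ENSG00000186918, GRCh38 chromosome 8, 28345585 to 28402701) rose from 10.4 ± 1.95 to 22.3 ± 1.71 CPM (SD, n = 3), 2.15-fold higher, with an SE of 0.11 on the log2 scale (edgeR adjusted p = 0.000115). This gene overlaps FBXO16 on the same strand (28348287 to 28490318), which fell from 41.2 ± 2.09 to 30.8 ± 1.61 CPM, a log2 fold change of -0.42. Their summed level was 51.6 ± 0.71 CPM in DMSO and 53.1 ± 0.64 in BPAF. C1QTNF3 went from 2.20 ± 1.03 to 4.78 ± 0.35 CPM (log2 fold change 1.11 ± 0.24). It overlaps the read-through gene C1QTNF3-AMACR, so its counts are uncertain. Rises were also called for the non-coding RNAs LINC02918 (1.06), LINC01355 (0.98), ZKSCAN2-DT (0.96) and PGLS-DT (0.87), all on the log2 scale. The remaining rises were those of the processed pseudogene RPS26P19 (0.98), YJEFN3 (0.90), the read-through gene RAB4B-EGLN2 (0.87) and CHST7 (0.85), which encodes a carbohydrate sulfotransferase. Of these 10, RPS26P19, YJEFN3 and RAB4B-EGLN2 share sequence with other genes and are uncertain. Only CHST7 had whole deposited counts in every library. The other rises, those of the non-coding RNAs included, held counts that were not whole, as did 64.4% of all tested genes, and may rest partly on shared reads.

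Among the 10 falls named under the same limit on expression, SULT1A4, which encodes a phenol sulfotransferase, had a log2 fold change of -1.08 ± 0.20 (SE). Its near-identical copy SULT1A3 was at 9.10 CPM in DMSO and 12.0 in BPAF, and the sum of both was 13.4 ± 1.95 and 14.1 ± 2.04 CPM, so the fall of one copy is uncertain. SMN2 fell by 0.45 on the log2 scale, and with its copy SMN1 the sum went from 99.8 ± 2.50 to 88.2 ± 1.38 CPM. The sums over these copies, and that of ZNF395 and FBXO16, were chosen after their values were seen. The spermidine and spermine acetyltransferase gene SAT1 fell by 0.48, RPL22L1, a paralogue of a ribosomal protein gene, by 0.42, SRBD1 by 0.39 and RPL30-AS1, antisense to a ribosomal protein gene, by 0.38 on the log2 scale. Of the 20 named genes, 9 passed in every fit with 1 library left out. C1QTNF3 did not pass without BPAF replicate 3 (edgeR adjusted p = 0.0704), and the calls of LINC02918, LINC01355, YJEFN3, RAB4B-EGLN2, PGLS-DT, CHST7, IER2, SAT1, SRBD1 and RPL30-AS1 were lost in 2 to 5 of the 6 fits, with adjusted p reaching 0.166. In DESeq2 without its filter, CHST7, PGLS-DT, RAB4B-EGLN2, RPL30-AS1, SAT1, SRBD1 and YJEFN3 did not pass either (adjusted p from 0.0605 to 0.163).

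**Figure D1:**
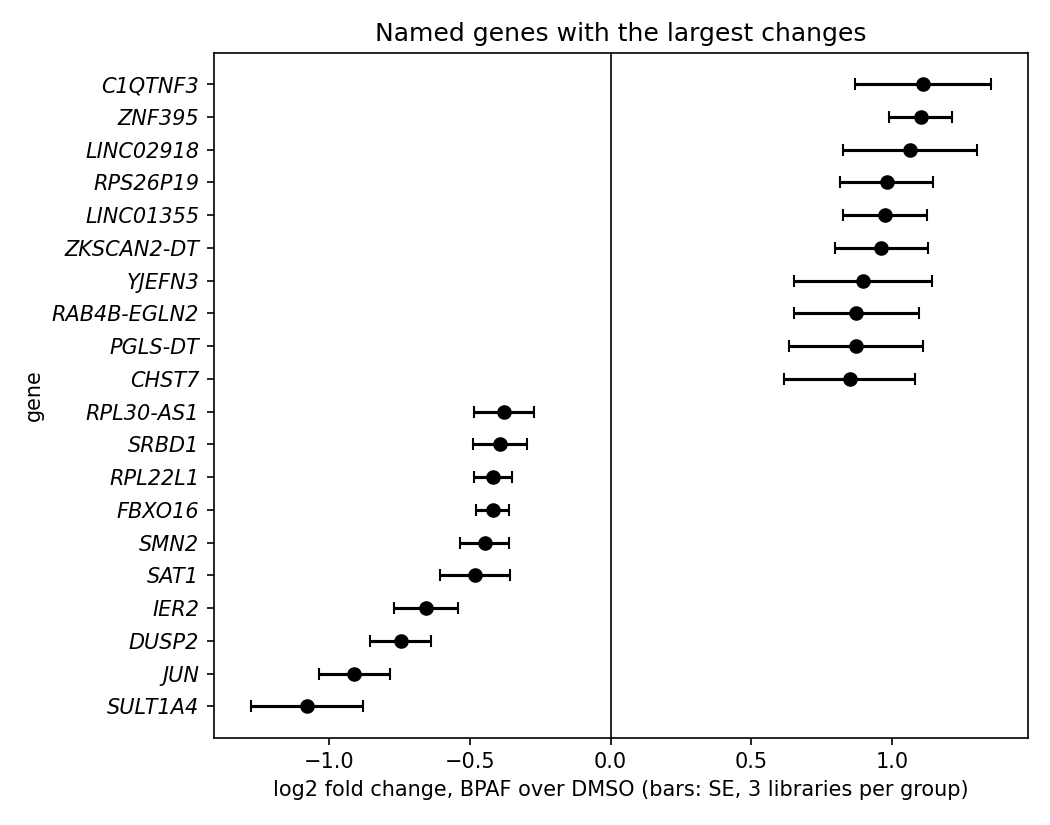
Log2 fold change of BPAF over DMSO (horizontal axis) for the 10 largest named rises and 10 largest named falls at an average log2 CPM of at least 1, with points for edgeR estimates and bars for the SE over 3 libraries per group. The rises run from 0.85 for CHST7 to 1.11 for C1QTNF3, and the falls from -0.38 for RPL30-AS1 to -1.08 for SULT1A4.

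Immediate early genes encode transcription factors and feedback regulators induced within minutes of receptor signalling. Of 34 tested members, 6 fell and 0 rose (10 fell when adjusted over the list alone), and 12 had a log2 fold change above 0. FOS, a subunit of the AP-1 transcription factor (ENSG00000170345, chromosome 14, 75278774 to 75282230), fell from 3.07 ± 0.55 to 0.66 ± 0.41 CPM (SD, n = 3), a log2 fold change of -2.23 ± 0.32 (SE, edgeR adjusted p = 0.000611). Its partner JUN (ENSG00000177606, chromosome 1, 58780788 to 58784327) fell from 12.8 ± 1.07 to 6.81 ± 1.28 CPM, a log2 fold change of -0.91 ± 0.13 (edgeR adjusted p = 0.000487). DUSP2, a phosphatase that inactivates MAP kinases (ENSG00000158050, chromosome 2, 96143166 to 96145440), fell from 33.3 ± 5.01 to 19.9 ± 2.00 CPM, and IER2 from 113.0 ± 9.41 to 71.8 ± 9.50 CPM. FOSB (log2 fold change -1.36) and EGR3 (-1.47) passed at levels near 1 CPM. EGR1 was at 58.4 ± 13.4 CPM in DMSO and 12.98 ± 6.79 in BPAF, a log2 fold change of -2.19 ± 0.40 with no overlap between groups, and did not pass in edgeR (adjusted p = 0.0644) but did in DESeq2 (8.61e-05, or 0.000174 without its filter) and limma-voom (0.000516). FOS, JUN and DUSP2 passed in each of the 6 fits with 1 library left out, whereas EGR3 passed in 0, IER2 in 1 and FOSB in 2, with adjusted p reaching 0.148. EGR1 passed without BPAF replicate 2 (0.0430). In DESeq2 without its filter, FOS, JUN and DUSP2 passed and EGR3 (adjusted p = 0.253) and FOSB (0.0995) did not.

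The whole immediate early list had a median log2 fold change of -0.14 (camera adjusted p = 0.000279; adjusted p = 0.380 with an estimated correlation and 0.102 in the rotation test). That median was -0.072 without BPAF replicate 1, -0.092 without DMSO replicate 3 and from -0.11 to -0.17 in the other 4 fits with 1 library left out. The list of T-cell activation and NFAT response genes shares DUSP2, EGR3, EGR1 and CD69 with it or with the NF-kB list, and 2 of its 20 tested members fell (camera adjusted p = 0.00412; adjusted p = 0.366 with an estimated correlation). CD69, an early surface marker of activation, was at 13.9 ± 0.66 CPM in DMSO and 11.2 ± 0.50 in BPAF (log2 fold change -0.30, edgeR adjusted p = 0.0530). Of 39 tested T-cell receptor complex and signalling genes, SIT1, an adaptor that dampens receptor signalling, was the 1 that fell, by 0.25 on the log2 scale (camera adjusted p = 0.0277; adjusted p = 0.380 with an estimated correlation). That list lost its call without DMSO replicate 2, BPAF replicate 1 or BPAF replicate 3, with adjusted p up to 0.119, and with protein-coding genes only (0.160). SIT1 lost its call without DMSO replicate 3 or BPAF replicate 1 (adjusted p up to 0.0853).

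**Figure D2:**
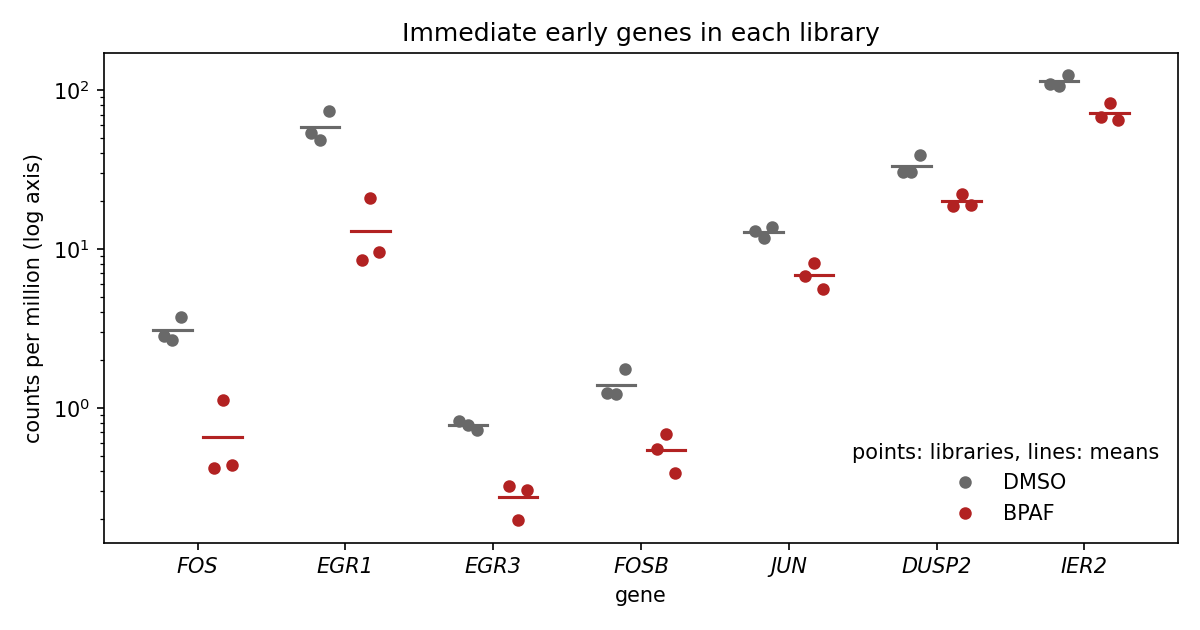
CPM (log axis) of 7 immediate early genes in each of the 3 DMSO and 3 BPAF libraries, with points for libraries and lines for group means. Every BPAF library lies below every DMSO library for each gene, with FOS at a mean of 3.07 in DMSO and 0.66 in BPAF.

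Estrogen receptor transcripts were scarce. ESR1, which encodes estrogen receptor alpha, had 11, 8 and 8 counts in DMSO and 3, 8 and 8 in BPAF, and GPER1, the G protein coupled estrogen receptor, had 6, 3 and 0 against 4, 3 and 8, both too few to test. ESR2, encoding estrogen receptor beta, was at 1.48 ± 0.32 CPM in DMSO and 1.55 ± 0.14 in BPAF (log2 fold change 0.07 ± 0.27, edgeR adjusted p = 0.928), and its sign changed in some alternative fits. The estrogen-related receptor gene ESRRA was at 33.8 ± 0.63 and 35.5 ± 3.16 CPM (0.08 ± 0.06, adjusted p = 0.566). The 11 tested members of the estrogen receptor and related nuclear receptor list gave 0 calls in edgeR, DESeq2 without its filter and limma-voom, with 1 unadjusted edgeR p under 0.05. Of these 11, 9 had a log2 fold change above 0 (median 0.07). The list did not pass in camera (adjusted p = 0.226, or adjusted p = 0.407 with an estimated correlation) but was called higher in the rotation test (adjusted p = 0.0425). Its median was -0.0067 with the length and GC offset, where the median of all genes was -0.043. Of 21 tested estrogen-responsive genes, EGR3 was the 1 that fell and 0 rose, and the list did not pass (camera adjusted p = 0.237); MYC was at 495.1 ± 21.0 and 466.3 ± 10.8 CPM (edgeR adjusted p = 0.120).

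Inflammatory gene groups gave few calls. With edgeR, 0 of 24 tested NF-kB target genes, 0 of 11 cytokine and chemokine genes, 0 of 32 cytokine and chemokine receptor genes and 0 of 46 interferon-stimulated genes passed, and the camera adjusted p of these lists was 0.491, 0.939, 0.691 and 0.565. DESeq2 without its filter and limma-voom gave 0 calls as well, and 3, 3, 4 and 3 members had an unadjusted edgeR p under 0.05. These lists held 43, 58, 50 and 50 symbols, so most cytokine and chemokine genes and many NF-kB targets were not tested. The members with the smallest p included IL15 (log2 fold change 0.61, edgeR adjusted p = 0.123), REL (0.20, 0.102) and CCR8 (-0.58, 0.173). Of 21 inflammasome and innate sensing genes, HMGB1, which encodes a chromatin protein that acts as an alarm signal when released, was the 1 that fell, by 0.20 on the log2 scale; the median of that list was 0.0066 while camera gave the direction as lower (adjusted p = 0.979). Among 19 MHC class I and II genes, B2M, the light chain of class I molecules, fell from 664.8 ± 25.2 to 561.4 ± 3.83 CPM (log2 fold change -0.24 ± 0.03, edgeR adjusted p = 0.000172), and the list did not pass (camera adjusted p = 0.484). The 28 T helper lineage regulators gave 0 calls in edgeR, DESeq2 without its filter and limma-voom, with 1 unadjusted edgeR p under 0.05 (camera adjusted p = 0.939).

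Most ribosomal protein and respiratory chain genes had log2 fold changes slightly below 0. Of 76 ribosomal protein genes, 36 fell and 0 rose (58 fell when adjusted over the list alone), 75 had a log2 fold change below 0, and the median was -0.17, or -0.089 with TPM, where the median of all genes was 0.045 to 0.086 (camera adjusted p = 1.50e-41; adjusted p = 0.378 with an estimated correlation). RPSA fell from 1778 ± 56.7 to 1541 ± 36.6 CPM (SD, n = 3), a log2 fold change of -0.21 ± 0.03 (SE, edgeR adjusted p = 0.000585), and RPL15 fell by 0.18 on the log2 scale. The share of counts from ribosomal protein genes was 6.01 ± 0.28% in DMSO and 5.51 ± 0.13% in BPAF (two-sided exact permutation p = 0.1, the smallest possible). Among 44 ribosome biogenesis genes, NPM1 (-0.20), GNL3 (-0.15), NOP16 (-0.20) and DDX18 (-0.10) fell. The list median was -0.05 (camera adjusted p = 6.35e-05, or adjusted p = 0.378 with an estimated correlation). With the length and GC offset that median was -0.086, where the median of all genes was -0.043. Of 58 nuclear-encoded respiratory chain genes, 14 fell, among them ATP5F1C (-0.30), NDUFA4 (-0.26), COX7B (-0.25) and COX6C (-0.23), with a median of -0.10 (camera adjusted p = 1.10e-13; adjusted p = 0.380 with an estimated correlation). Of 15 mitochondrially encoded genes, MT-ND5 was the 1 that fell in edgeR, by 0.17, against 6 in DESeq2, 5 in limma-voom and 6 in edgeR when adjusted over the list alone (camera adjusted p = 0.000178; adjusted p = 0.463 with an estimated correlation). MT-RNR2 had a log2 fold change of -0.43 and did not pass in edgeR (adjusted p = 0.0983) but did in DESeq2 (0.00138) and limma-voom (0.00261), as did MT-CO1 (-0.10) and MT-ND6 (-0.18). NOP16, DDX18 and MT-ND5 lost their calls in 4, 5 and 4 of the 6 fits with 1 library left out, with adjusted p up to 0.178, and NOP16 and DDX18 did not pass in DESeq2 without its filter (0.0699 and 0.0560). With TPM, DDX18 had a log2 fold change of 0.013. Some deposited counts were not whole for RPSA, RPL15, ATP5F1C, COX7B and COX6C, whereas all were whole for NDUFA4. The same held for 61.7% of the genes called lower and 64.4% of all tested genes, which had counts that were not whole. Whether shared reads contributed to these falls was not tested.

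**Figure D3:**
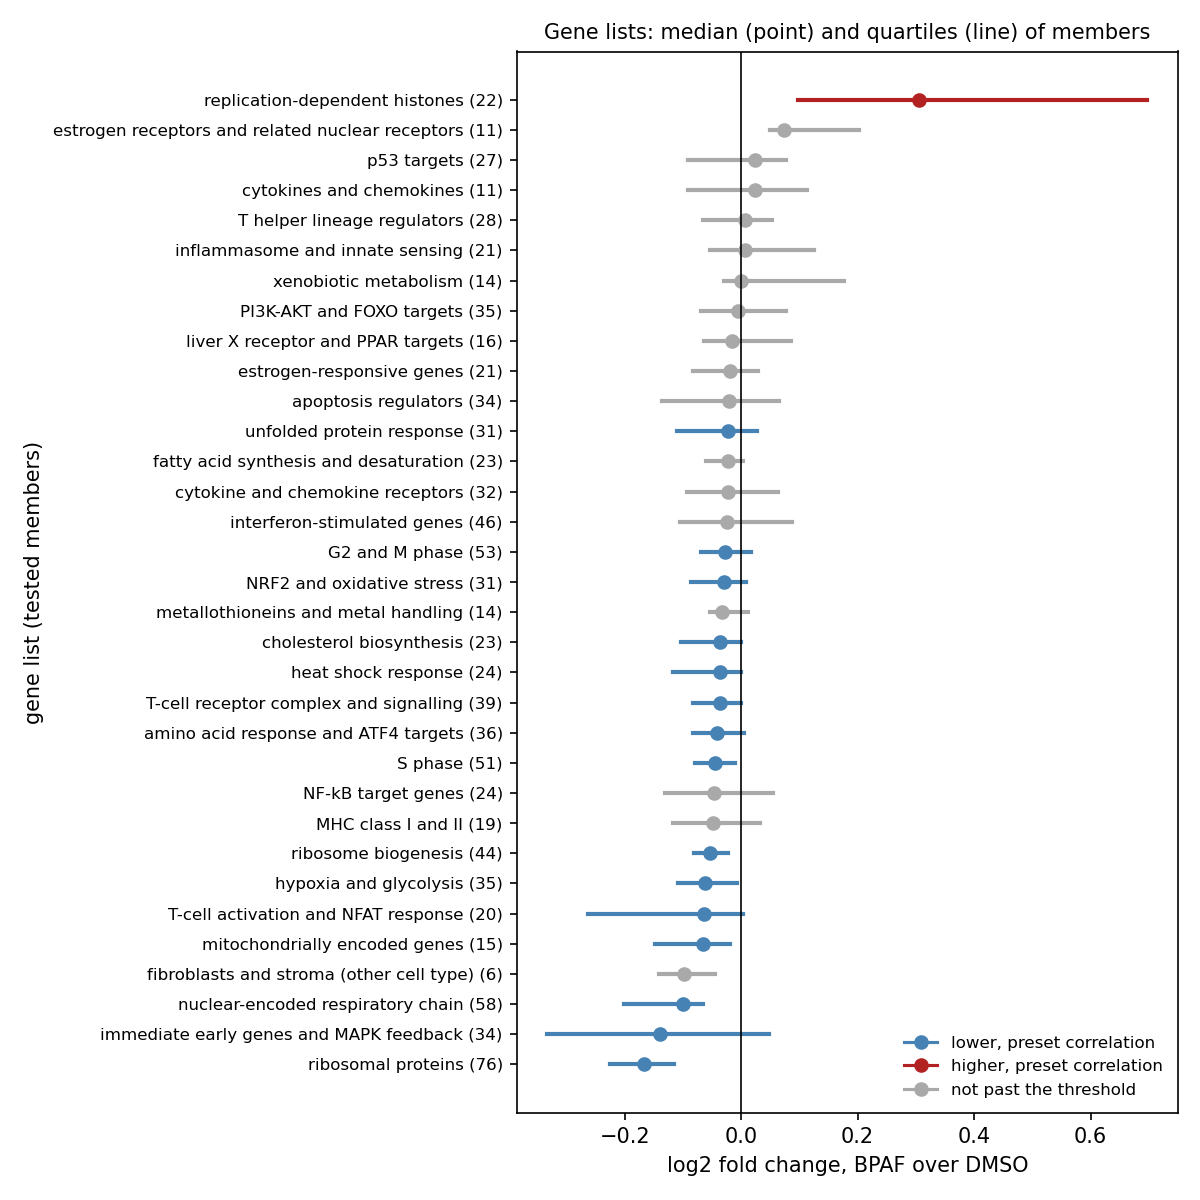
Median (points) and quartiles (lines) of member log2 fold changes, BPAF over DMSO, for the 33 tested gene lists, coloured by the camera result with a preset correlation. The ribosomal protein list has the lowest median at -0.17 and the replication-dependent histone list the highest at 0.31. With an estimated correlation 0 of the 16 called lists passed, and the smallest camera adjusted p of any list was 0.366.

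In cholesterol biosynthesis, 4 of 23 tested genes fell: HMGCS1 (-0.19), which encodes an early enzyme of the mevalonate pathway, IDI1 (-0.21), FDFT1 (-0.13) and MSMO1 (-0.17) (camera adjusted p = 0.000840; adjusted p = 0.366 with an estimated correlation). Of 35 hypoxia and glycolysis genes, 4 fell, including ENO1 (-0.12) and TPI1 (-0.12), and EGLN1, the oxygen-sensing prolyl hydroxylase, rose by 0.63 (camera adjusted p = 0.00249; adjusted p = 0.380 with an estimated correlation). The heat shock response list held 3 falls in 24 genes, HSPA8 (-0.18), DNAJA1 (-0.13) and HSF2 (-0.23) (camera adjusted p = 0.00412; adjusted p = 0.591 with an estimated correlation). PPP1R15A (-0.31), HSPA5 (-0.17) and SEC61B (-0.18) fell among 31 unfolded protein response genes (camera adjusted p = 0.0127; adjusted p = 0.378 with an estimated correlation). ATF4 (-0.18) and SLC38A2 (-0.15) fell among 36 amino acid response and ATF4 target genes (camera adjusted p = 0.0116; adjusted p = 0.501 with an estimated correlation). Of 31 NRF2 and oxidative stress genes, 4 fell, including TXN (-0.24) and PRDX3 (-0.12), and the ferritin heavy chain gene FTH1 rose by 0.17 (camera adjusted p = 0.0276; adjusted p = 0.407 with an estimated correlation). Calls were lost without DMSO replicate 1 for the hypoxia (0.0608), heat shock, ATF4 and NRF2 lists, and without BPAF replicate 3 for the heat shock, ATF4 and NRF2 lists, with adjusted p up to 0.178. The ATF4 list also lost its call without DMSO replicate 2 and the NRF2 list without BPAF replicate 1. With protein-coding genes only, the unfolded protein response (0.0921), ATF4 (0.0858) and NRF2 (0.207) lists did not pass. HMGCS1, IDI1, HSPA8, ATF4, SLC38A2 and FTH1 passed in each of the 6 fits with 1 library left out, and the other genes named here lost their call in 1 to 5 of them. In DESeq2 without its filter, MSMO1, HSF2, PPP1R15A and SEC61B did not pass (adjusted p from 0.0687 to 0.119).

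The S phase and the G2 and M phase lists had medians slightly below 0. Of 51 S phase genes, PCNA (-0.16), the sliding clamp of DNA replication, RRM1 (-0.15) and MCM7 (-0.11) fell (camera adjusted p = 0.000292; adjusted p = 0.366 with an estimated correlation). Of 53 G2 and M phase genes, 8 fell, including the spindle checkpoint gene MAD2L1 (-0.27), CDK1 (-0.15) and CKS2 (-0.17) (camera adjusted p = 0.0147; adjusted p = 0.380 with an estimated correlation). Replication-dependent histone genes were the 1 list called higher, with a median of 0.31 over 22 tested members (camera adjusted p = 0.0479; adjusted p = 0.378 with an estimated correlation), although H3C8 was the 1 member that rose, from 0.22 ± 0.11 to 0.78 ± 0.13 CPM (SD, n = 3). These transcripts mostly lack poly(A) tails, and the libraries were selected for poly(A). The histone list lost its call with the CPM filter (camera adjusted p = 0.644) and without DMSO replicate 2 or BPAF replicate 1 (adjusted p up to 0.149), the G2 and M phase list without DMSO replicate 1 or DMSO replicate 2 (up to 0.0608) and with protein-coding genes only (0.172), and MCM7, CDK1, CKS2 and H3C8 in 1 to 5 of the 6 fits. H3C8 did not pass in DESeq2 without its filter (adjusted p = 0.155).

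Of 34 tested apoptosis regulators 5 fell, among them MCL1 (-0.20), CYCS (-0.16), BID (-0.16) and PMAIP1 (-0.21), and the list did not pass (camera adjusted p = 0.240). TRIAP1 (-0.27) and PMAIP1 fell among 27 p53 target genes, whose median was 0.02 while camera gave the direction as lower (adjusted p = 0.939). The list of 35 PI3K-AKT and FOXO target genes did not pass (camera adjusted p = 0.792). TFRC, the transferrin receptor gene, fell by 0.15 among 14 metal handling genes (camera adjusted p = 0.237). BID and TFRC lost their calls without BPAF replicate 1 (adjusted p = 0.0671 and 0.0711) and PMAIP1 without DMSO replicate 2, BPAF replicate 1 or BPAF replicate 2 (up to 0.0665), and PMAIP1 (0.0604) did not pass in DESeq2 without its filter. With TPM, the log2 fold changes were 0.013 for CYCS and 0.019 for TFRC. No gene passed among 14 xenobiotic metabolism, 23 fatty acid synthesis or 16 liver X receptor and PPAR target genes in edgeR (camera adjusted p = 0.671, 0.185 and 0.877), where 4, 3 and 5 had an unadjusted p under 0.05. DESeq2 without its filter called 1 fatty acid gene, SCD (-0.10, adjusted p = 0.0252), and limma-voom called 0. The fatty acid list was called lower with the length and GC offset (camera adjusted p = 0.00578), where camera was not run on voom values. Without the offset and with an estimated correlation its camera adjusted p was 0.380. Across all lists, 106 of 929 tested genes changed, 3 upward and 103 downward.

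Rises outnumbered falls among long non-coding RNAs, pseudogenes and assembled loci. Of 2089 tested long non-coding RNA genes, 107 rose and 11 fell, and 72.0% had a log2 fold change above 0, with a median of 0.17. Of 660 pseudogenes, 49 rose and 2 fell (median 0.12), and of 129 assembled loci, 8 rose and 0 fell (median 0.18), while 231 of 12335 protein-coding genes rose and 511 fell (median -0.01). With the length and GC offset, 125 protein-coding genes rose and 1177 fell (median -0.05), against 109 and 18 for long non-coding RNAs (0.14) and 48 and 6 for pseudogenes (0.08). The median of all genes was -0.043 in that fit. NEAT1, the RNA scaffold of paraspeckles, rose from 113.0 ± 5.58 to 132.3 ± 7.67 CPM (SD, n = 3), a log2 fold change of 0.23 ± 0.04 (SE, edgeR adjusted p = 0.00629), while MALAT1 was at 576.4 ± 11.1 and 590.3 ± 20.9 CPM (adjusted p = 0.590). NEAT1 and MALAT1 were singled out after their values were seen. Long non-coding RNA genes took 1.62 ± 0.01% of counts in DMSO and 1.78 ± 0.04% in BPAF, and pseudogenes 1.07 ± 0.01% and 1.16 ± 0.02% (two-sided exact permutation p = 0.1 for each, the smallest possible). Beside these rises, 538 genes of families taken as silent in T cells, such as olfactory receptors, summed to 20.5, 22.2 and 20.1 CPM without TMM scaling in DMSO and 27.5, 25.5 and 27.1 in BPAF. These genes were chosen by family name. The most abundant of them held 292 counts over all libraries, where the whole set held 1334 in DMSO and 1719 in BPAF, so the set was not strictly silent.

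**Figure D4:**
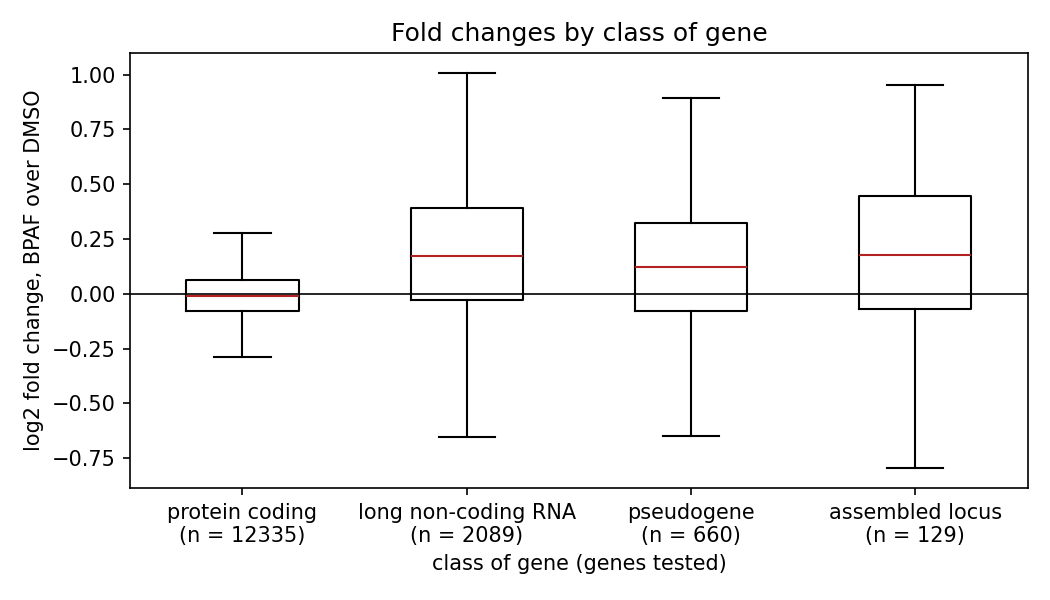
Log2 fold change, BPAF over DMSO (vertical axis), of all tested genes by class, with boxes for quartiles, red lines for medians and whiskers to the farthest gene within 1.5 box lengths, outlying genes not drawn. Medians are -0.01 for protein-coding genes, 0.17 for long non-coding RNAs, 0.12 for pseudogenes and 0.18 for assembled loci.

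Few markers of other cell types were expressed, and they gave 0 calls in edgeR, DESeq2 without its filter and limma-voom, with 0 unadjusted edgeR p under 0.05. Of the marker lists, 2 B cell, 1 myeloid, 3 epithelial, 6 fibroblast and 3 erythroid genes were expressed enough to test. The most abundant were AIF1 (81.3 ± 5.82 CPM in DMSO, 78.8 ± 2.88 in BPAF), CD79A (13.8 ± 1.21 and 12.2 ± 0.41) and BLK (11.6 ± 0.65 and 12.3 ± 0.18), and the fibroblast list, the 1 with enough members for camera, did not pass (adjusted p = 0.427).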

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

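The length and GC offset, the gene-class restrictions and DESeq2 without independent filtering were chosen after the data had been seen. Against 938 changed genes with edgeR, other scalings, filters, DESeq2 and limma-voom gave 631 to 1291, and 1488 were called with the length and GC offset. The filter of DESeq2 gave an adjusted p to 6765 of 30134 genes, those with a mean count above 671, and so to 0 of FOS, JUN, DUSP2 and ZNF395, and 243 of the 938 genes had none. Without that filter DESeq2 called 550 of the 15490 genes and 441 of the 30134, with 13 changed at least 2-fold in each. The TPM settings gave 1 gene (pseudocount 1), 2 (pseudocount 0.1) and 0 (no filter), while 2520, 2522 and 3100 genes had an unadjusted p under 0.05; the cause was not tested. Leaving out 1 library gave 322 to 861. Against 28 genes changed at least 2-fold, 78 were called without a filter (30134 genes tested), 1 with DESeq2, 0, 1 and 0 with TPM (same order), 12 among protein-coding genes (12335 tested) and 11 to 44 with 1 library left out, the extremes without BPAF replicate 1 and BPAF replicate 2. Against 16 gene lists, 0 passed with an estimated correlation, where the smallest camera adjusted p of any list was 0.366. In the rotation test 3 lists passed (adjusted p = 0.0425 for each): T-cell activation and S phase, which were among the 16, and the estrogen receptor list, called higher, which was not. The other 14 of the 16 lost their call there, ribosomal proteins among them (0.115); the cause was not tested. The CPM filter gave 15 lists, all lower, and 11 were called with protein-coding genes only. The 106 changed list members became 41 to 143 with 1 library left out, with 41 without BPAF replicate 1, 55 without BPAF replicate 3 and 58 without DMSO replicate 1. Same-numbered libraries did not deviate together (correlations 0.0010, -0.043 and 0.014 across genes). With 3 libraries per group this cannot exclude that they were handled in pairs. The replicate number as a block gave 826 genes, 16 lists and 92 list members.

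Of 3416 comparisons of 187 named genes and lists with an alternative, 2833 kept direction and side of the threshold, 421 kept direction but no longer passed, 71 newly passed and 91 reversed, 60 of these under TPM. The 15 that had passed in edgeR were all under TPM, for 5 genes that were lower with counts. TPM raised the median of all genes to 0.079, 0.086 or 0.045 (pseudocount 1, 0.1 and no filter). With TPM, the log2 fold changes of these 5 were 0.0063 (TXNRD1), 0.013 (CYCS and DDX18), 0.016 (LDHA) and 0.019 (TFRC). Genes that had not passed and turned positive were AIF1 0.0066, CCNG1 0.042 to 0.043, COL1A1 0.0013, CXCR4 0.0061, GSTP1 0.0016, HACD3 0.011, HADHA 0.011, IKZF2 0.079 to 0.081, MYB 0.016, MYD88 0.041 to 0.042, PTPRC 0.060, SEL1L 0.157 to 0.164 and SLC39A10 0.178 to 0.187. TGFB3 turned to -0.275 to -0.315, TIGAR to -0.027 to -0.028 and ESR2 (no filter) to -0.092. With the length and GC offset, ESR2 was -0.0067, MTOR -0.0040 and TAL1 -0.0060, and list medians were -0.053 (T helper regulators), -0.065 (cytokine receptors), -0.049 (inflammasome) and -0.020 (p53). The median of all genes was -0.043 in that fit, so ESR2, MTOR, TAL1 and the p53 list lay above it and the other 3 list medians below it. With protein-coding genes only, list medians were 0.0060 (PI3K-AKT), 0.018 (inflammasome), -0.0053 (liver X receptor) and 0.035 (p53), and with the CPM filter 0.0071 (inflammasome). With 1 library left out, ranges were -0.073 to 0.235 for ESR2, -0.210 to 0.148 for ESRP1, -0.151 to 0.027 for HBB and -0.334 to 0.088 for TAGLN, and medians ran from -0.049 to -0.011 (cytokine receptors), 0.0067 to 0.062 (cytokines), -0.0085 to 0.036 (inflammasome), -0.012 to 0.021 (p53) and -0.0085 to 0.029 (T helper regulators). For lists, the direction that reversed is that of camera. In the fits where their direction reversed, these lists had adjusted p above 0.5, and the cause was not tested. ESR1 and GPER1 had too few counts to test, with a highest TPM of 0.13 and 0.58.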

Other observations

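All values in this part on shared reads, on the ZNF395 locus and on the neighbour of DUSP2 come from tests chosen after the result was seen, as did the calculation of an even spread over exons. The other tests were set before their results were seen.

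A long non-coding RNA gene without a symbol (ENSG00000228873, chromosome 2, 96145602 to 96147012), beside DUSP2 on the same strand, fell with it, from 27.0 ± 3.29 to 5.79 ± 2.84 CPM (SD, n = 3), a log2 fold change of -2.24 ± 0.33 (SE, edgeR adjusted p = 0.0341). It was lower in every BPAF library than in every DMSO library. Of 26 tested short-lived transcripts outside the immediate early list, MCL1 fell by 0.20 and CCNL1 by 0.15 on the log2 scale (edgeR adjusted p = 0.00153 and 0.0101), and ID1 rose by 0.41, from 15.2 ± 1.71 to 20.2 ± 2.23 CPM (0.0154).

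The real grouping of the 6 libraries gave 938 changed genes, against at most 4 in the other 9 splits, so 1 of the 10 splits gave as many. For genes changed at least 2-fold it gave 28 against at most 4, and for gene lists 16 against at most 9, again 1 of 10 splits in each case. With 10 splits the share cannot fall under 0.05.

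Of 34 tested immediate early genes, 6 fell and 12 had a log2 fold change above 0, and the list, called lower in camera with a preset correlation, did not pass with an estimated one (adjusted p = 0.380). A general fall of short-lived transcripts, which would lower any quickly decaying RNA, is argued against by 26 tested short-lived transcripts outside the list. Their median log2 fold change was 0.033 (SD 0.19), with 14 above 0, where at most -0.2 was predicted. That prediction asked for a larger fall than the immediate early list's own median of -0.14. Half-lives were not measured in these cells, so the argument covers these 26 transcripts only. A single library is argued against too, since the call with the preset correlation was kept in 6 of 6 fits without 1 library. A response of the cells to BPAF remains a hypothesis, and handling or harvest of the 2 groups at different moments may act on the same genes and was not tested.

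Of 76 ribosomal protein and 58 respiratory chain mRNAs, 36 and 14 fell, with neither list past the threshold at an estimated correlation (adjusted p = 0.378 and 0.380), while 107 of 2089 long non-coding RNA genes rose. Bias by annotated exon length and GC content as the whole cause is argued against. With the length and GC offset, the ribosomal protein median was -0.20 (SD 0.07). The median of all genes was -0.043 in that fit, so part of the -0.20 is a common shift. Exon length was the union of all annotated exons, 7222 nt for RPL15 and 4825 nt for RPL10, which can exceed the length of the expressed transcripts. The offset therefore could not decide on a bias by transcript length, which stays open. Genomic DNA in the BPAF libraries stays open: the summed level of the genes taken as silent in T cells was 1.28 times as high in BPAF (95% exact binomial interval 1.19 to 1.38, covering counting error only), above the 1.1 set beforehand. Spread evenly over exon length, that rise would give 133.3 CPM to long non-coding RNAs, 8.34% of the 1599 CPM by which they rose, a calculation that assumes even coverage and excludes nothing. More nuclear RNA in the BPAF libraries may also contribute and was not decided. The 21 tested nuclear-retained RNAs had a median of 0.074, short of the 0.1 predicted, with 15 above 0. Of these 21, 4 were called higher and 0 lower.

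Near-identical copies and overlapping genes were among the genes called higher. Reads shared between gene copies may account for part of them: 88.6% of the 411 genes called higher had a count that was not whole, against 62.3% of genes matched on mean expression (odds ratio 4.68, Fisher exact p = 9.32e-19). At ZNF395, reads divided differently between overlapping genes may account for the rise, because the log2 ratio of its summed level with FBXO16 was 0.041 where ZNF395 alone was 2.15-fold higher. Among the 574 tested long non-coding RNA genes whose counts were all whole, 15 rose and 2 fell, with a median of 0.17, against 107 and 11 of all 2089, and among pseudogenes with whole counts 1 of 95 rose, with a median of 0.18, against 49 of all 660, with a median of 0.12; the difference of these shares was not tested. A change in transcript choice at these loci stays open. The ratio of count to TPM changed in 0 of 9635 genes with limma (912 had an unadjusted p under 0.05). How TPM was computed is not given, so whether that ratio follows the mix of transcript lengths within genes is not known. Genes with low counts or low TPM were left out of it. C1QTNF3, RPS26P19, YJEFN3, RAB4B-EGLN2 and SULT1A4 were among those left out, so the ratio decides nothing for them.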
